A study of Mus musculus with 4 samples.

How the data were processed

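Footpad RNA of 4 adult mouse samples, 2 wild type and 2 Tabby, was compared with a common reference on 2-colour Agilent oligonucleotide arrays. Per the labels, footpad RNA carried Cy3 and the reference Cy5 on every array, with no dye swap, so a dye effect of a probe is shared by both groups and drops out of their difference. The files place all 4 arrays on 1 slide with 1 scan, WT at positions 1 and 2 and Tabby at positions 3 and 4, so position on the slide and genotype cannot be told apart. The labels number the samples within a group and do not say whether they came from separate animals, so the p-values measure only the spread between these samples.

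Per the file headers, the arrays were read with Agilent Feature Extraction 9.5.1.1. The deposited scanner files give the mean intensity and the median background intensity of each spot as scanned, and a processed intensity that the software had subtracted, detrended and dye-normalized, per the file headers. The deposited log ratio is the log10 of processed Cy5 over processed Cy3. The software had set it to 0 at 8.9%, 11.6%, 9.65% and 14.6% of the spots of WT 1, WT 2, Tabby 1 and Tabby 2, all of which were not well above background in either channel. The authors' value table holds 25164 spots on a log10 scale. It was matched to the scanner files by spot number, and each of its columns equals the footpad over reference log10 ratio plus the mean log10 reference signal of the 4 arrays, with a median difference of at most 4.1e-05. Its column medians were 2.60 for WT 1, 2.60 for WT 2, 2.59 for Tabby 1 and 2.60 for Tabby 2. How its spots were chosen is not given in the sources used here. It served as an alternative.

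The probes were compared by their array IDs. The gene name and systematic name columns repeat the probe ID, and the description and position of the probes name no gene or locus, so gene names were not used here. The reference table of mouse genes holds no sequences and none of its names could be joined to the probe IDs. For this reason 0 of the 29 fixed gene lists were tested, the Eda level was not analysed here as a check of the genotype labels, and the choice of 1 probe per gene name had no effect. The rule for named features was the largest falls and rises with an adjusted p under 0.05, a gene symbol, and both arrays of one group on the same side of both of the other. It was applied without the symbol and limited to 2 probes in each direction. The text gives each probe's sequence of 60 bases as the array design lists it.

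The spot intensities were read with limma 3.58.1 in R 4.3.3. Background was corrected with normexp on the mean signal and median background with an offset of 50, which draws the ratios of dim probes toward 0. Log ratios were normalized by loess within each array, with weight 0 for the 1417 control spots, which were then left out. Spots with an outlier flag were left out, from 1 spot on WT 1 to 9 on Tabby 2. Spots of the same probe were averaged, giving 42006 probes. Ratios were turned to footpad over reference on the log2 scale, and differences are Tabby minus WT.

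A probe was tested if its Cy3 signal was well above background on both arrays of at least 1 group. This left out 13631 probes, and 2 more had no value left in a group without their outlier spots. The test was a two-sided moderated test (lmFit and eBayes with a constant prior), adjusted by Benjamini-Hochberg over the 28373 tested probes, with group as the only term. The prior had 3.69 degrees of freedom and an SD of 0.13 log2. A probe not well above background on any array of a group has only a bound there. The bound sets the mean of the brighter group against the dimmer group's mean of, on each array, the higher of the lowest signal among probes well above background and the probe's own signal. It uses the Cy3 channel after loess and Aquantile normalization and is open to dye bias where the lowest signal, which comes from other probes, stands in for the probe's own, since the probe's dye effect then does not drop out. It leaves out the change in the reference channel, so it can lie above the fitted fold change and is not a strict limit.

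The fit was tested on simulated log2 ratios of 28373 probes around the real WT means. Each probe had 1 SD, drawn from limma's fitted prior and shared by both groups. It called 54% of the probes changed 2-fold and 99% of those changed 4-fold, all with the right sign, and 5.56% of its calls were false. The real groups differed in spread, with a median SD of 0.075 log2 between WT arrays and 0.12 log2 between Tabby arrays. The false share therefore describes limma's own model and is not an error rate of the real data. Probes of overlapping sequence were found with BLAST+ 2.17.0 (word size 11), keeping identical stretches of at least 20 bases on the same strand. Figures were drawn with matplotlib 3.10.9.

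The groups, the test and most alternatives were set before the data were examined. The rule for named probes was set then too, but was changed as given above because the probes had no gene names. Leaving out spots with an outlier flag was not part of the fixed design and followed a first fit that kept them, which also called 405 probes. The alternatives changed the background correction, the normalization, the use of the reference, the filter on dim probes, the prior, the threshold and the block, left out each array in turn, and used the authors' value table. Array weights, the authors' probes with the values used here, and keeping the spots with an outlier flag were chosen after seeing the data. Slide was not run as a block because there was 1 slide.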

Results

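Gene expression was measured in adult mouse footpads, the bare skin pads of the paw that hold the sweat glands. The samples came from male mice of the C57BL/6 strain, either wild type or Tabby, a mutant of Eda. Eda encodes ectodysplasin, a signalling protein of the tumour necrosis factor family that skin appendages need for their development, and Tabby mice lack sweat glands. Each of the 4 arrays carried footpad RNA of 1 sample in Cy3 and a common reference RNA, a pool of cultured mouse cell lines with added embryonic stem cell RNA, in Cy5. There were 2 wild-type samples, called WT 1 and WT 2, and 2 Tabby samples, called Tabby 1 and Tabby 2. The age label was 10 weeks for Tabby 1 and 9 weeks for each of the other arrays, while the series text gives 8 weeks for the adult samples. The development stage label of WT 1 read P5, while its title and age label said adult, and it was kept as an adult sample.

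The Cy3 signal was well above background at 72.0% of the non-control spots on WT 1, 67.3% on WT 2, 71.1% on Tabby 1 and 64.7% on Tabby 2. No non-control spot was saturated in either channel. The number of arrays limits the precision: the median SD over probes was 0.075 log2 between the WT arrays and 0.12 log2 between the Tabby arrays. Across the tested probes, which are not independent replicates, the log2 ratios of WT 1 and WT 2 correlated with r = 0.991, and 32 probes lay at least 2-fold apart between them. The corresponding values for Tabby 1 and Tabby 2 were r = 0.974 and 268 probes. The 7 probes printed in 5 copies had a median SD between copies of 0.085 to 0.09 log2 within an array.

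The series asks which genes depend on Eda in the sweat gland, and in these adult footpads most of the differences were falls. The arrays measured whole footpads, so the absence of gland tissue and a lower level of a gene within a cell cannot be told apart here. Of 28373 probes tested, 385 were lower and 20 were higher in Tabby than in WT (limma, Benjamini-Hochberg adjusted p under 0.05). The fall was at least 2-fold for 319 of the lower probes, at least 4-fold for 114, at least 8-fold for 43 and at least 16-fold for 12, with dim probes counted at their bound. The median fall of the 385 probes was 2.79-fold. The 20 higher probes changed less, with a median rise of 2.09-fold, and 11 of them rose at least 2-fold. For all 405 of these probes both Tabby arrays lay on the same side of both WT arrays, which their selection by the test nearly requires. Among all tested probes this held for 43.1%, where chance gives 33.3%. The fold change of all tested probes had a median of 0.014 log2, and 3189 probes had an unadjusted p under 0.05, of which 2042 were lower and 1147 higher in Tabby. No single probe can reach significance by permutation, since 2 arrays against 2 allow no two-sided p under 0.333, so the calls rest on the spread that limma shares across probes. Each array weighed on the count: 128 probes passed without WT 1, 227 without WT 2, 913 without Tabby 1 and 2298 without Tabby 2. The calls were 128 lower and 0 higher without WT 1, 213 and 14 without WT 2, 633 and 280 without Tabby 1, and 1268 and 1030 without Tabby 2.

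**Figure D1:**
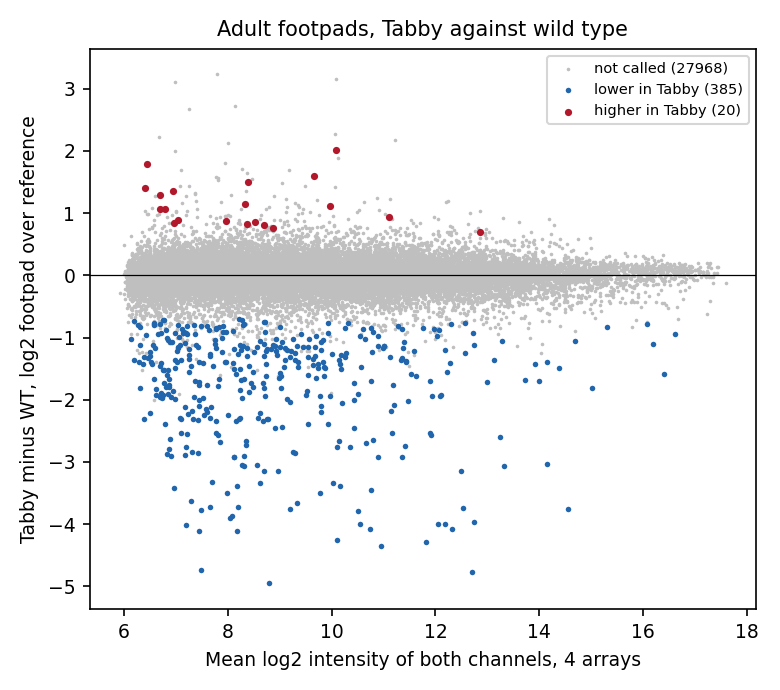
Difference between Tabby and WT in log2 footpad over reference (vertical axis) against the mean log2 intensity of both channels over the 4 arrays (horizontal axis), 1 point per tested probe, with probes past the adjusted p in blue (lower in Tabby) or red (higher in Tabby). The 385 lower probes cover the range of intensities and reach below -4, while the 20 higher probes stay near or below 2.

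Probe Z00025366-1 had the largest fitted fall among the called probes. Its sequence is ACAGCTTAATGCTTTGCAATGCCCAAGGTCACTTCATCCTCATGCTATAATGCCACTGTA. Its log2 ratio of footpad over reference was 3.97 ± 0.30 in WT (SD, n = 2) and -0.98 ± 0.78 in Tabby (SD, n = 2), so that the footpad signal lay above the reference in WT and below it in Tabby. A dye effect of the probe would be part of both levels and drops out only of their difference. Z00025366-1 fell by 4.95 on the log2 scale (SE 0.37, limma adjusted p = 0.0046), a 30.9-fold difference. With the Cy3 channel alone, scaled to the 75th percentile, the change of Z00025366-1 was -6.03.

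Probe Z00074275-1, with the sequence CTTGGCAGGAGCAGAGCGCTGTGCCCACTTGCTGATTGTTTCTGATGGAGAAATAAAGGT, was named next by the same rule. Its log2 ratio was 4.57 on WT 1 and 4.58 on WT 2, against -0.80 on Tabby 1 and 0.43 on Tabby 2. Z00074275-1 fell by 4.76 on the log2 scale (SE 0.38, limma adjusted p = 0.0056). Its change was -5.38 without Tabby 2 and -4.15 without Tabby 1. Both probes were well above background in Cy3 on all 4 arrays, so neither value is a bound. The order of the 2 falls is not settled: without WT 1 the change was -4.77 for Z00074275-1 and -4.74 for Z00025366-1, and with Cy3 alone and quantile normalization it was -4.75 and -4.73.

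Probe Z00006534-1, with the sequence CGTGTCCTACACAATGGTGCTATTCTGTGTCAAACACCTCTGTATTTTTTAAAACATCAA, had the largest fitted rise among the called probes. Its log2 ratio was -0.21 ± 0.06 in WT and 1.80 ± 0.40 in Tabby (SD, n = 2 each), a difference of 2.01 (SE 0.20, limma adjusted p = 0.012). Probe Z00026029-1, with the sequence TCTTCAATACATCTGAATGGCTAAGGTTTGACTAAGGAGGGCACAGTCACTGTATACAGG, was not well above background in Cy3 on either WT array and was well above it on both Tabby arrays. By the bound in Cy3 it was at least 3.06-fold higher in Tabby, and its fitted change was 1.79 log2, or 3.45-fold (limma adjusted p = 0.0078). The rank of these rises is not settled, since Z00026029-1 and 2 other called rises, with Cy3 bounds of 2.89-fold and 3.86-fold, have only a bound. The fitted rise of these 2 was no larger than that of Z00026029-1. The bound of 3.86-fold thus lies above its probe's fitted rise and is not a firm lower limit. With Cy3 alone at the 75th percentile the fitted change of Z00026029-1, which depends on how dim signals are treated, was 5.82 log2 against 2.22 for Z00006534-1, and with the scanner log ratio it was 5.72 against 2.10. Neither rise passed the threshold without WT 1, with limma adjusted p = 0.078 for Z00006534-1 and 0.058 for Z00026029-1.

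In WT footpads 238 of the 385 lower probes, 61.8%, were at least 2-fold above the common reference, compared with 18.1% of all tested probes. The WT values enter both sides of this comparison, so it describes the lower probes and is not a separate test. With no dye swap, a dye effect of a probe also stays in its level over the reference. In Tabby footpads 54 of the 385, 14.0%, were at least 2-fold above the reference, compared with 4953 of all 28373 tested probes. The Tabby values also enter the choice of the lower probes, so this too is only a description. The median change of the lower probes in the footpad channel was -1.52 log2, and that in the reference channel was 0.0057 log2. For the 20 higher probes these medians were 1.12 and 0.072 log2.

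Of the 385 lower probes, 22 were not well above background in Cy3 on either Tabby array, and a further 17 on 1 of them. These 22 probes had Cy3 bounds of 1.53-fold to 11.7-fold lower in Tabby, with a median bound of 3.03-fold. Of the 20 higher probes, 3 were not well above background on either WT array, with bounds from 2.89-fold to 3.86-fold.

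Probes of overlapping sequence show how far a change depends on a single probe, for the probes that have such a partner. In 670 pairs of tested probes that shared at least 20 bases on the same strand, the log2 changes correlated with r = 0.972 across pairs, which are not independent replicates. The lower probes had 27 such partners, all of which had a negative change, and 26 of the 27 were themselves among the lower probes. Where both probes of a pair were lower, each is the partner of the other and both are counted, so the 26 are not separate checks. The higher probes had 0 such partners.

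Of the 268 probes at least 2-fold apart between the Tabby arrays, 183 were higher and 85 lower on Tabby 1, compared with 14 higher and 18 lower on WT 1 between the WT arrays. Against the WT mean, on Tabby 1, 440 probes were at least 2-fold below and 209 at least 2-fold above, and on Tabby 2 the numbers were 376 and 94. Both Tabby arrays were at least 2-fold below the WT mean at 316 probes and at least 2-fold above it at 21.

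**Figure D2:**
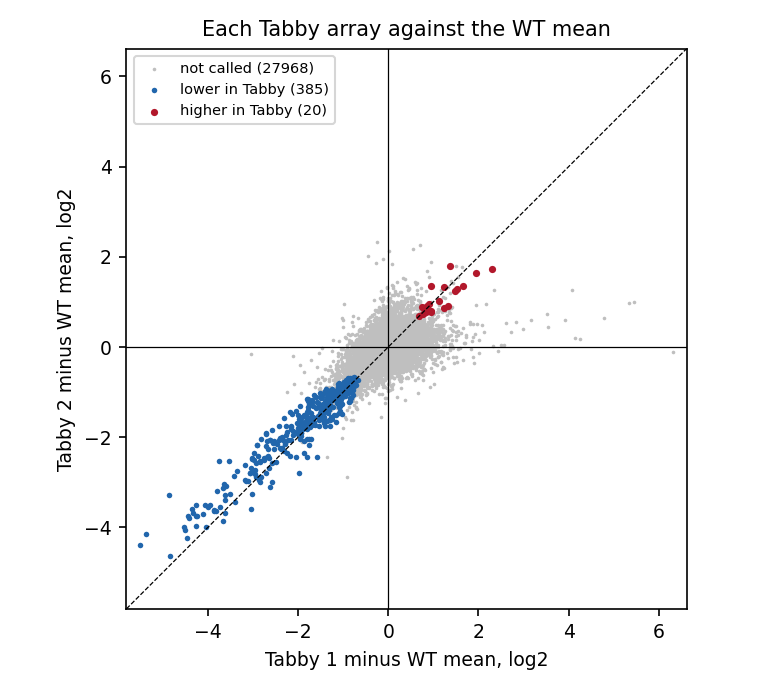
Log2 footpad over reference of Tabby 1 minus the WT mean (horizontal axis) against that of Tabby 2 minus the WT mean (vertical axis), 1 point per tested probe, with the dashed line marking equal values and the called probes in blue (lower) and red (higher). The 385 lower probes lie below 0 on both axes, and both named falls lie off the dashed line, deeper on Tabby 1 than on Tabby 2. Some uncalled probes extend to the right at values near 0 on Tabby 2.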

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

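Array weights, the authors' probes with the present values and keeping outlier spots were chosen after seeing the data. All 385 lower probes kept a negative change and all 20 higher probes a positive one in each alternative that tested them, except 1 lower probe with the scanner log ratio and 1 with the authors' value table. For most alternatives this was fixed in advance. The groups lie apart at these probes, so leaving out an array or changing the filter, prior, threshold, block or weights cannot turn a sign. Only alternatives with other values could have done so. Fewer were called again: of the 20 higher probes, 3 with the scanner log ratio, 6 with median centring, 11 with Cy3 alone at the 75th percentile, 4 without WT 2 and 0 without WT 1, and 3 of the 14 in the authors' table; of the 385 lower, 215, 308, 284, 205 and 128, and 163 of the 262 in that table. The count of lower probes stayed within 1.5 times of 385 in each alternative not named next. With the values of the authors' table, the probes that passed numbered 213, 201 lower and 12 higher. The present values on the same 17675 probes gave 284. Fewer probes thus account for part of the drop, and the scanner log ratio for the rest. The count of higher probes was 11 with the scanner log ratio, 8 with median centring, 32 with Cy3 alone at the 75th percentile and 35 with a robust intensity trend in the prior; the cause was not tested. By construction it was 55 at an adjusted p under 0.1 and 11 with a minimum of 2-fold. Leaving out each array gave 128 to 2298 probes, 128 to 1268 lower and 0 to 1030 higher, with the lone array assumed to vary like the other group; without WT 1 none of the higher probes passed, where 20 did with all arrays. Each named fall passed under all 18 alternatives fitted, and each named rise missed the threshold once, without WT 1. With the number as a replicate block, 665 probes passed, 582 lower and 83 higher. The samples share only a number: deviations of same-numbered arrays correlated with r = 0.22 across probes, with 2 pairs. Aquantile leaves a log ratio unchanged, and the gene name choices changed nothing since each probe is its own name, so these test nothing. The gene list test, with or without an estimated correlation, and a slide block were not run. Signal over background limits 22 of the lower probes to a bound.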

Other observations

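The tests of uneven Tabby arrays, of the normalization and of the stage label of WT 1 were chosen after the result was seen.

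With 385 probes lower and 20 higher in Tabby, rises hidden by the larger spread between the Tabby arrays are argued against as the whole cause for changes of at least 2-fold, since 381 of the 456 such probes, 83.6%, were lower whatever their p. They could still add to the imbalance, as 64 of the 75 rises and 61 of the 381 falls of that size were not called. Of those 64 rises, 32 were at least 2-fold higher on Tabby 1 than on each other array. Tabby 2 can be higher than WT at such a probe too: at Z00024153-1 it lay at 0.51 log2, against 0.06 on WT 1 and -0.06 on WT 2, with 1.80 on Tabby 1. This is a single example, and how many of the 32 have Tabby 2 above both WT arrays was not counted. For changes of at least 1.5-fold and under 2-fold the explanation stays open and the values go with it. Of these probes 448 were lower, 59.0%, and 311 higher, while 65 lower and 9 higher ones were called. Among calls of any size, falls made up a smaller share when a Tabby array was left out than when a WT array was. Each of those fits rests on 1 array in a group. Across 6 other background corrections and normalizations, at least 92.2% of the calls were lower. They include the authors' table, which holds the scanner log ratio on fewer probes and so is no separate check from it. The fullest of 16 equal blocks of the array held 7.53% of the lower probes where an even spread gives 6.25%, which argues against a region of the array. Position on the slide cannot be told apart from genotype, and genotype stays open and untested.

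On Tabby 1, 96 probes were at least 2-fold higher than on each of the other arrays, compared with 26 on Tabby 2, 9 on WT 1 and 0 on WT 2. For 8 of the 96 the gap to each other array was at least 8-fold, and the widest was 77.7-fold; none of the 96 was among the called probes. Faulty spots could not be excluded: only 2 probes of overlapping sequence exist for these, and both, 100%, were at least 0.5 log2 up on Tabby 1. The fullest of 16 blocks of the array held 12.5% of the probes, at the limit set beforehand, and 25.1% of 10000 random draws of 96 tested probes gave a block as full. These values argue against a flaw in 1 block as the source of most of the 96 probes, while a flaw behind a smaller part of them stays open. An older animal or other tissue in the sample may be the source, but only 1 array has the 10-week label, which the series text does not give, so age, dissection and array cannot be told apart.

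The stage label of WT 1 reads P5. If WT 1 were not adult tissue, it would likely stand farthest from the other arrays, but 19 probes on WT 1 were at least 2-fold away from each other array, fewer than the 114 on Tabby 1 and the 35 on Tabby 2. The WT pair also had the highest correlation of the 6 pairs of arrays, r = 0.991. Other values run the opposite way: WT 2 had 0 such probes, and WT 1 had more probes at least 2-fold apart from Tabby 1 and Tabby 2, 740 and 559, than WT 2 had, 624 and 429. The first values argue against WT 1 alone being of a stage far from that of WT 2, while a smaller difference, or a stage shared by both WT arrays, was not tested.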
